A study of Bradyrhizobium diazoefficiens USDA 110 with 4 samples.

How the data were processed

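Per the labels' protocols, total RNA of Bradyrhizobium diazoefficiens was extracted with hot phenol, copied to cDNA with random hexamers, and labelled with Cy3 or Cy5. A salt and a control sample were hybridised together on each of 4 two-colour arrays. The deposited values are 1 log ratio per probe and array. Their normalization, the base of the logarithm, the background correction and the direction are not given in the sources used here. Medians lie close to 0 on each array, and scale, base and direction stay unknown. The spread between arrays 1 and 2 equals 1.30% per array if the base is 2 and 4.40% if it is 10, and that between arrays 3 and 4 equals 1.08% and 3.63%. The labels name salt and control extracts 1 to 3 and the dye of each, and no label says how the salt was applied or for how long. Spot intensities were not analysed here, so no probe could be judged against background. The number of arrays limits the precision, and so does the correlation within arrays 1 and 2 and within arrays 3 and 4.

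The design had foreseen turning the sign of arrays with salt in Cy3 unless arrays of opposite dye orientation correlated above 0. They did, so no sign was turned. The design had assumed a base of 2, and the same tests were run with the base left open. Of 8480 probes, 198 lacked a value on at least 1 array and were left out, each array was centred on its median, and probes of the same locus were averaged, leaving 8078 genes. Among 187 loci with several probes, 82 had probes of opposite sign and 11 had probes that differed by more than 0.1. Gene symbols came from the platform annotation held by GEO: 8462 probes had 1 symbol there, 0 had several and 18 were not listed. For 1469 probes the symbol is a gene name and not a locus number, which left 1420 genes for the lists. Locus numbers follow the order of genes on the chromosome and the letter before them gives the strand. Coordinates are not used here, because the locus names were not matched to a current assembly.

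Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment), with a salt coefficient and a dye term. Arrays that share an extract by the labels were to be a random block (duplicateCorrelation, statmod 1.5.0). That correlation could not be estimated together with the dye term on 4 arrays. Without the dye term it was -0.60, and a negative value was set to 0. The prior degrees of freedom were 2.77 beside 2 residual ones. Gene lists were tested with camera (preset inter-gene correlation of 0.01, then an estimated one) and with fry. With an estimated correlation camera uses only the 2 residual degrees of freedom, so it had little power here. With the preset correlation its degrees of freedom come from the number of genes, so those p-values do not measure the spread between arrays. P-values were adjusted over 16 lists with at least 5 genes. Of 28 lists, 5 had fewer genes (trehalose; potassium and sodium transport; mechanosensitive channels; efflux; iron). For the other 7 (betaine, proline and ectoine; oxidative stress; tRNA synthetases; outer membrane; tricarboxylic acid cycle; ABC transport; transposases) no symbol matched, since product descriptions are not used here.

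The grouping of samples, the tests, the lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule took, per direction, genes past the test and then those with the largest mean among genes of one sign on 4 arrays, up to 12, plus up to 4 members of each list with the lowest p. Genes without a symbol were named only among the top 4 of a direction, and the report describes a part of the list members so chosen. Alternatives concerned the dye term, the block, centring, scaling, probes with missing values, variance moderation, thresholds and each array left out in turn. Alternatives added after the data were seen took arrays 1 and 2, and arrays 3 and 4, as blocks or averages, tested each probe apart, turned the sign of arrays with salt in Cy3, and grouped genes by the first letters of their symbols.

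The steps were tested on simulated data with 50 planted changes of each of 4 sizes among 8078 genes, using each gene's own spread over the 4 arrays, and with a further shift of -0.05 planted in the 46 flagellar genes. With independent noise the limma fit recovered 62% of changes of 0.1 log units, 82% of 0.2, 98% of 0.3 and 100% of 0.4, with 9 false calls among the 7833 genes outside both planted sets. With noise correlated at 0.80 within arrays 1 and 2 and within arrays 3 and 4, it recovered 76%, 84%, 94% and 96%, with 54 false calls, and 15.6% of unchanged genes had an unadjusted p under 0.05 and 32.1% had one sign on all 4 arrays. Planted changes had the same size on all 4 arrays, and their number loosens the adjusted cutoff for every gene. The shares recovered are therefore no detection rates for the data. There flgD (blr6997), with -0.19 ± 0.014 (SD, n = 4), did not pass. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.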

Results

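Gene expression was compared between salt-treated and control cultures of Bradyrhizobium diazoefficiens, the soybean root-nodule symbiont long known as B. japonicum, which fixes nitrogen inside root nodules. Per the series' design text there were 3 biological replicates on 4 arrays with a dye swap. The labels name 3 salt and 3 control RNA extracts. Array 1 held salt extract 2 in Cy5 against control extract 1 in Cy3, and array 3 held salt extract 3 in Cy5 against control extract 2 in Cy3. Array 2 held salt extract 1 in Cy3 against control extract 2 in Cy5, and array 4 held salt extract 2 in Cy3 against control extract 3 in Cy5. The arrays carried 8480 probes, and 8078 genes had values on all 4 arrays. The 4 arrays limit the precision.

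Values are log ratios whose base the sources used here do not state, so they are given as log units. Arrays of opposite dye orientation correlated above 0, so the values were taken as already turned by treatment, although a dye bias in values that were not turned would also correlate above 0. Which group was the numerator is not stated. Titles name the salt treatment, so a positive value is taken as likely a higher transcript level in salt, and every sign given here reverses if control was the numerator. If the values were not turned, 0 genes and 0 lists pass, with an adjusted p of 0.422 for ribosomal proteins and 0.355 for flagellar genes. Deposited medians were 0.00021, -0.0017, -0.0052 and -0.0044 on arrays 1 to 4. The SDs over probes were 0.056, 0.059, 0.053 and 0.054.

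To examine how the transcriptome responded to salt, the 4 log ratios of each gene were tested against 0. The locus blr4637 rose by a mean of 0.37 ± 0.031 log units (SD, n = 4 arrays; SE 0.017), positive on 4 of 4 arrays, with values of 0.34, 0.35, 0.40 and 0.39. This equals 1.29-fold if the base is 2 and 2.34-fold if it is 10. Of the 8078 genes, 1 passed an adjusted p of 0.05 in limma, namely blr4637 (adjusted p = 0.0440). At an unadjusted p under 0.05 there were 1357 genes, 713 positive and 644 negative, or 16.8% of genes. Independent arrays with no effect would give 403.9 genes, but simulated unchanged genes whose noise was shared within arrays 1 and 2 and within arrays 3 and 4 had such a p in 15.6% of cases. The adjusted p of blr4637 was 0.0362 without array 1, 0.242 without array 2, 0.0586 without array 3 and 0.265 without array 4. A fit with an array left out has fewer residual degrees of freedom than the 2 of the full fit. The adjusted p was 0.362 with arrays 1 and 2 averaged and arrays 3 and 4 averaged, and 0.0114 with those pairs as random blocks. Both alternatives were added after the data were seen. The adjusted p was 0.345 with robust and trended moderation, 0.0760 with scale normalization, 0.0204 with quantile normalization and 0.620 with a shared-extract correlation fixed at 0.5. A fit with no dye term called 561 genes, 318 positive and 243 negative, and in the same simulation that fit made 353 false calls. The simulation also held planted changes, which loosen the adjusted cutoff, so 353 is not a count for data with no change.

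Positive values on 4 of 4 arrays were led, after blr4637, by genes that did not pass the test. The gene dop (blr2591) had a mean of 0.30 ± 0.25 (SD, n = 4; adjusted p = 0.238), with 0.020 on array 1 and 0.52 on array 4. The locus blr6074 had 0.28 ± 0.10 (adjusted p = 0.0974). The gene napD (blr7037), which serves the assembly of periplasmic nitrate reductase, had 0.26 ± 0.082 (adjusted p = 0.0948). The cytochrome gene cycB (blr6128) had 0.23 ± 0.15 (adjusted p = 0.175). The other 7 of the 12 largest positive means lay between 0.21 and 0.25 and belonged to loci with no symbol.

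Negative values on 4 of 4 arrays were led by blr4700, with a mean of -0.29 ± 0.11 (SD, n = 4; adjusted p = 0.104), blr0095, with -0.28 ± 0.070 (adjusted p = 0.0810), and bll7538, with -0.26 ± 0.18 (adjusted p = 0.181). The flagellar rod gene flgC (bll5813) had -0.25 ± 0.23 (adjusted p = 0.270), with -0.47 on array 1 and -0.052 on array 4. The Nod factor acyltransferase gene nodA (blr2025) had -0.20 ± 0.16 (adjusted p = 0.230). The hook-capping gene flgD (blr6997) had -0.19 ± 0.014 (adjusted p = 0.0666), the smallest SD among these. None of the 12 largest negative means passed the test. One sign on all 4 arrays was held by 2884 genes (35.7%), 1417 positive and 1467 negative, where independent arrays with no effect would give 12.5% and simulated unchanged genes with noise shared within the array pairs gave 32.1%.

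**Figure D1:**
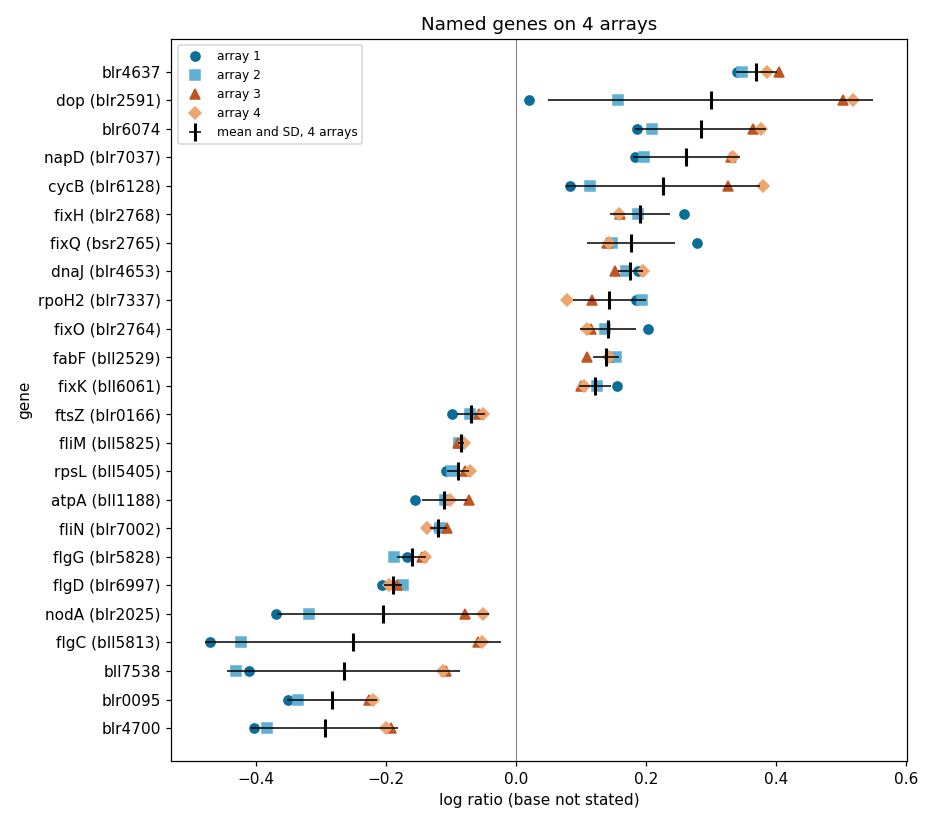
Log ratios (base not stated) of 24 named genes, 1 marker per array, with the mean and SD of 4 arrays in black. The locus blr4637 lies between 0.34 and 0.40 on all 4 arrays, while flgC reaches -0.47 on array 1 and -0.052 on array 4.

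Lists of ribosomal protein, ATP synthase, respiratory complex I and mixed cell wall and division genes lay below the other genes in the test with a preset correlation. Among 52 ribosomal protein genes 51 had negative means, the median was -0.047, and 36 were negative on 4 of 4 arrays. Examples are rpsL (bll5405), with -0.089 ± 0.017 (SD, n = 4), and rpsF (bll4079), with -0.064 ± 0.0062. All 8 ATP synthase genes had negative means (median -0.049), with -0.11 ± 0.034 for atpA (bll1188), and so had all 13 genes of respiratory complex I (median -0.022), with -0.058 ± 0.0044 for nuoF (bll3137). Cell wall and division genes had a median of -0.021 over 16 members, 12 of them negative, with -0.069 ± 0.021 for the division gene ftsZ (blr0166). In limma's camera test with a preset correlation of 0.01 the adjusted p was 3.04e-16 for ribosomal proteins, 0.000212 for ATP synthase, 0.00151 for complex I and 0.0226 for cell wall and division. The preset form draws its degrees of freedom from the number of genes, so these p-values do not measure the spread between arrays. With an estimated correlation the adjusted p was 0.224, 0.391, 0.469 and 0.438 in the same order. That form of the test has 2 residual degrees of freedom, so a lost call does not show correlation between genes. For ribosomal proteins the estimated correlation was 0.011, near the preset value, and the unadjusted camera p still went from 1.90e-17 to 0.0140. The estimate was -0.084 for ATP synthase, 0.33 for complex I and -0.042 for cell wall and division. In fry the adjusted p was 0.0103 for ribosomal proteins, 0.0506 for ATP synthase, 0.0925 for complex I and 0.00873 for cell wall and division. Of the members, 28 ribosomal protein genes, 4 ATP synthase genes, 2 complex I genes and 0 cell wall and division genes passed when adjusted over the list alone, all negative, and 0 passed when adjusted over all genes tested. The cell wall and division list had an adjusted p of 0.0877 without array 3 and 0.0813 without array 4.

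Motility genes also had mainly negative values. Of 46 flagellar genes 35 had negative means, the median was -0.024, and 24 were negative on 4 of 4 arrays against 3 positive. The rod gene flgG (blr5828) had -0.16 ± 0.022 (SD, n = 4), the motor switch genes fliN (blr7002) and fliM (bll5825) had -0.12 ± 0.013 and -0.085 ± 0.0043. Other genes of symbol flgG (bll6873) and fliN (bll6879) had -0.030 ± 0.047 and 0.010 ± 0.064. They lie among 24 flagellar genes at loci 6850 to 6885, grouped after the values were seen, whose median was -0.011. The camera adjusted p of the flagellar list was 7.94e-06, and 0.391 with an estimated correlation. The estimate was 0.041, and the adjusted p in fry was 0.0506. When adjusted over the list alone 11 flagellar genes passed, all negative, and 0 passed over all genes tested. All 11 chemotaxis genes had negative means (median -0.036), with -0.067 ± 0.029 for the methyltransferase gene cheR (blr2196). Their medians were 0.030 and 0.023 on arrays 1 and 2 and -0.083 and -0.11 on arrays 3 and 4. The camera adjusted p for chemotaxis was 0.0226, and 0.658 with an estimated correlation, 0.479 without array 3 and 0.687 without array 4. The estimated correlation was 0.99, far above the preset 0.01, and the adjusted p in fry was 0.495. No chemotaxis gene passed when adjusted over the list alone or over all genes tested.

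A list of cyc and fix genes for cytochromes c and the cbb3 oxidase, and a list of chaperone and protease genes, lay above the other genes in the test with a preset correlation. Of the 13 cytochrome list genes 10 had positive values on 4 of 4 arrays, and the median was 0.055. Beside cycB these include fixO (blr2764), a subunit of the high-affinity cbb3 oxidase, with 0.14 ± 0.043 (SD, n = 4), and cyc1 (blr7488), with 0.059 ± 0.011. The camera adjusted p was 0.00382, and 0.469 with an estimated correlation. The estimate was 0.19, above the preset 0.01, and the adjusted p in fry was 0.0925. When adjusted over the list alone 2 passed, both positive, and 0 over all genes tested. The list holds fixN (blr2763), fixO and fixP (blr2766), which are near neighbours, beside 10 cyc genes. Those cyc genes alone, grouped after the values were seen, had a median of 0.034, with 7 positive and 3 negative means. Their camera adjusted p over 79 symbol groups was 0.129, and 0.852 with an estimated correlation. The 11 cox genes of other cytochrome oxidases, which this list does not hold and which were grouped after the values were seen, had a median of -0.039, with 9 negative means. Of 34 chaperone and protease genes 24 had positive means (median 0.016), among them dnaJ (blr4653), with 0.18 ± 0.019, dnaK (blr0678), with 0.059 ± 0.035, and the protease adaptor gene clpS (bll2636), with 0.050 ± 0.0070. The chaperonin genes groES and groEL went the other way in 7 of 10 cases, 4 of them negative on 4 of 4 arrays, such as groEL (blr7533), with -0.043 ± 0.033; these were singled out after their values were seen. The medians of the chaperone list were 0.058 and 0.054 on arrays 1 and 2 and -0.0097 and -0.0070 on arrays 3 and 4. The camera adjusted p was 0.0247, and 0.658 with an estimated correlation, 0.611 without array 1 and 0.498 without array 2. The estimated correlation was 0.30, above the preset 0.01, and the adjusted p in fry was 0.370. When adjusted over the list alone 1 chaperone gene passed, positive, and 0 over all genes tested.

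The remaining 8 lists did not pass the camera test. Among 37 nitrogen fixation genes the median was 0.0047 (adjusted p = 0.118). The adjusted p was 0.00582, 0.0171, 0.156 and 0.474 without arrays 1, 2, 3 and 4 in turn, and the median was -0.0015 without array 3 and -0.0029 without array 4. It was 0.0154 with arrays that share an extract averaged, 0.0391 with arrays 1 and 2 and arrays 3 and 4 as random blocks, 0.0533 with those pairs averaged, and 0.584 with an estimated correlation. Of its members 4 passed when adjusted over the list alone, all positive: fixH (blr2768), with 0.19 ± 0.047 (SD, n = 4), fixQ (bsr2765), with 0.18 ± 0.067, fixO, with 0.14 ± 0.043, and the regulator gene fixK (bll6061), with 0.12 ± 0.025. Other genes of symbol fixK had -0.030 (bll2757), 0.026 (bll2109) and 0.0086 (bll7696). All 4 are fix genes, and fixO is also in the cytochrome list. The 15 nif genes, grouped after the values were seen, had a median of -0.0061, with 6 positive means (camera adjusted p = 0.769). Among 16 fatty acid genes the median was -0.025 (adjusted p = 0.0640), with fabF (bll2529) at 0.14 ± 0.020 and fabI (blr3459) at 0.098 ± 0.013 against fabG (blr4083) at -0.077 ± 0.029 and a second fabF (blr4085) at -0.063 ± 0.0089; over the list alone 2 positive and 4 negative passed. This list had an adjusted p of 0.0474 with scale and 0.0477 with quantile normalization, and 0.469 with an estimated correlation. Among 6 sigma factor genes the median was 0.020 (adjusted p = 0.125), and the heat-shock sigma factor gene rpoH2 (blr7337), with 0.14 ± 0.056, passed when adjusted over the list alone. Nodulation genes (31, median -0.0018, adjusted p = 0.712), type III secretion genes (10, median -0.014, adjusted p = 0.504) and polyhydroxybutyrate genes (5, median 0.011, adjusted p = 0.448) had no member that passed when adjusted over the list alone. Exopolysaccharide genes (6) had a median of -0.00027 but a mean of 0.0090 and a test direction above the other genes (adjusted p = 0.694), with 0 members past the test over the list alone. DNA repair genes (14) had a median of 0.00084 and a test direction below the other genes (adjusted p = 0.857), and 2 positive and 1 negative passed over the list alone. Over all genes tested 0 members of these 8 lists passed.

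**Figure D2:**
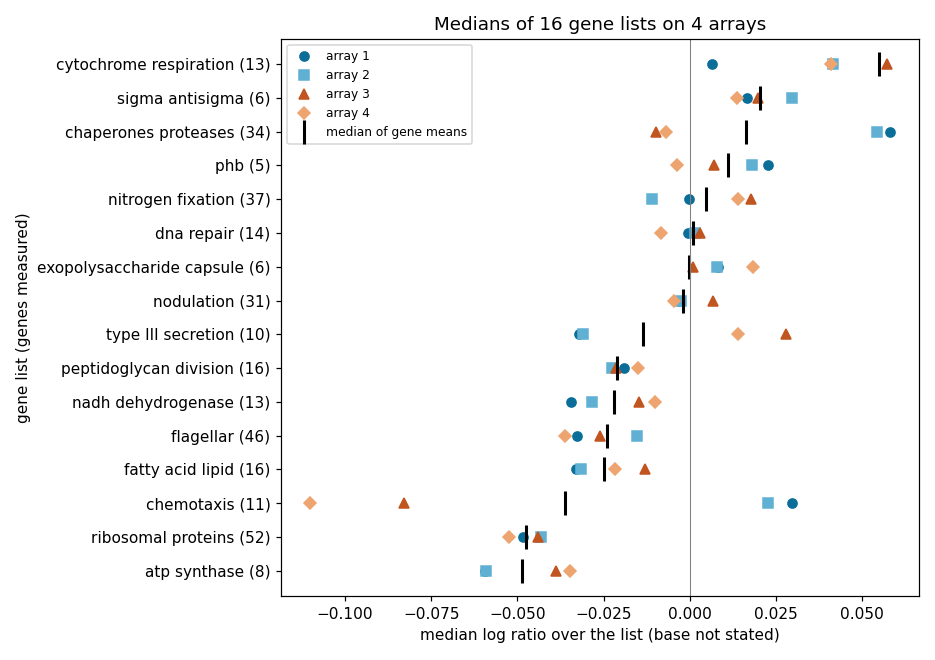
Median log ratio (base not stated) of 16 gene lists on each of 4 arrays, with the number of genes measured in parentheses and the median of the gene means as a black bar. Ribosomal protein medians lie between -0.043 and -0.052 on the 4 arrays, while chemotaxis medians are 0.030 and 0.023 on arrays 1 and 2 and -0.083 and -0.11 on arrays 3 and 4.

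Lists of 1 to 4 genes were too short for a set test and are given gene by gene. The trehalose synthesis genes otsA (bll0322) and otsB (bll0323) had 0.032 ± 0.065 (SD, n = 4; adjusted p = 0.621) and 0.046 ± 0.032 (adjusted p = 0.262). The potassium uptake genes kdpA (bll6779), kdpB (bll6778) and kdpC (bll6777) had -0.023 ± 0.010, 0.018 ± 0.015 and -0.0078 ± 0.0095, and mrp (blr3742) had -0.036 ± 0.025. The mechanosensitive channel gene mscL (bll5071) had 0.0052 ± 0.015. The efflux genes acrA (blr1515), acrB (blr1516) and hlyD (bll6292) had -0.075 ± 0.015, -0.038 ± 0.023 and 0.0098 ± 0.0087. The iron and haem genes irr (bll0768), fur (bll0797), hemE (bll2399) and tonB (bll7071) had -0.013 ± 0.046, -0.0079 ± 0.035, -0.019 ± 0.027 and -0.0042 ± 0.053. None of these passed the test over all genes, and when adjusted over the list alone acrA passed (adjusted p = 0.00695) and the others did not.

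The dye swap was used to ask whether genes differed between dye orientations. In limma 0 of the 8078 genes had a dye effect past an adjusted p of 0.05, and 0 had an unadjusted p under 0.05, fewer than the 403.9 that chance gives. The residual of this fit holds the difference between arrays 1 and 2 and arrays 3 and 4, with an SD over genes of 0.034 against 0.0095 for the dye contrast, so the test could not detect dye effects and does not show that there were none. With those arrays as random blocks 0 genes passed and 19 had an unadjusted p under 0.05. The 4 arrays were then compared with each other across genes, which are not independent replicates. Pearson's r was 0.828 (Spearman 0.752) for arrays 1 and 2 and 0.888 (0.773) for arrays 3 and 4. Arrays with a shared extract had lower values, 0.187 (0.207) for arrays 1 and 4, which share salt extract 2, and 0.161 (0.170) for arrays 2 and 3, which share control extract 2. The remaining pairs had 0.128 (0.079) for arrays 1 and 3 and 0.165 (0.139) for arrays 2 and 4. The limma p-values treat the 4 arrays as independent, so with this grouping of arrays they are too small for genes that differ between the array pairs. In the simulation with noise shared in that way 54 of 7833 unchanged genes were called, with planted changes loosening the adjusted cutoff.

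**Figure D3:**
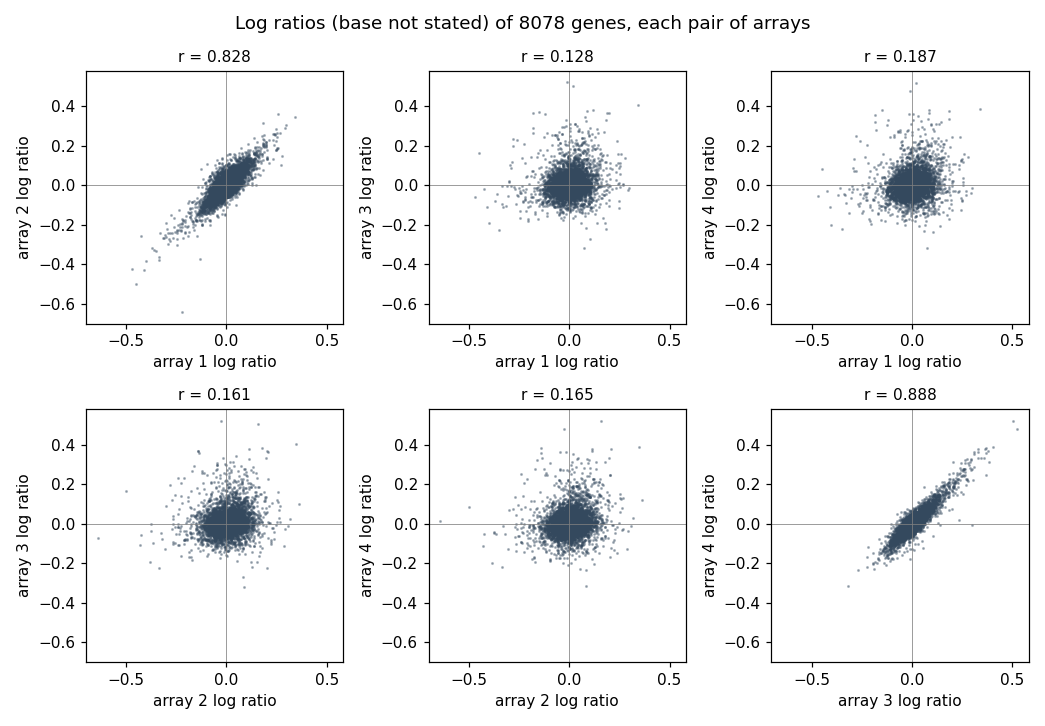
Log ratios (base not stated) of 8078 genes for each of the 6 pairs of arrays, 1 point per gene, with Pearson's r above each panel. The points form a narrow diagonal for arrays 1 and 2 (r = 0.828) and for arrays 3 and 4 (r = 0.888), and a round cloud for the other pairs (r from 0.128 to 0.187).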

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

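The tests of array structure in this part were chosen after the values were seen. In 3 of 98 named genes 1 of the 4 arrays stood apart from the others, and none of the 16 list medians did. The cutoff marks about 5% of groups of independent values. These arrays are correlated in pairs and many genes were named for a low p or a shared sign, so 5% is not the chance rate here. For fixQ (bsr2765) array 1 had 0.28 against 0.14 to 0.15 on the others, a gap of 0.942 of the whole range. For the DNA repair gene recF (bll0827) array 2 had 0.12 against 0.046 to 0.056, a gap of 0.874. For the complex I gene nuoN (bll4904) array 1 had -0.044 against -0.015 to -0.019, a gap of 0.872.

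Arrays 1 and 2, and arrays 3 and 4, resembled each other far more than arrays that share an extract by the labels, with a mean r of 0.858 against 0.174. Whether the extract labels are right was not tested. Bias of single spots is argued against by chromosomal neighbours: for the difference between the array pairs, same-strand neighbours correlated more than opposite-strand neighbours by 0.167 (95% bootstrap interval 0.1004 to 0.227), as genes of one operon would. Opposite-strand neighbours, which share no operon, still correlated at 0.123, and the source of that part was not tested. Whether both arrays of a pair held the same RNA with dyes exchanged cannot be told apart from other sources, because the pairs gave different answers. The same-strand excess was 0.143 (95% bootstrap interval 0.0959 to 0.189) for array 1 minus array 2, which excludes 0. For array 3 minus array 4 it was 0.0066 (-0.0366 to 0.0567), which includes 0. A difference between cultures or days, or a bias that follows spot intensity, is open and was not tested.

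The values shared by all 4 arrays, which carry the salt comparison, showed the same excess between neighbours, 0.202 (95% bootstrap interval 0.146 to 0.257). This argues against bias of single spots as their whole source. Opposite-strand neighbours still correlated at 0.158, and the source of that part was not tested. Differences between cultures would give the excess too. With noise shared within array pairs 32.1% of simulated unchanged genes held one sign against 35.7% seen. A dye bias that follows transcript abundance, in values not turned by dye, stays open: the part of the values that followed dye orientation had an SD over genes of 0.233 times that of the mean of 4 arrays, as already turned values would also give, its neighbour excess was 0.0820 (0.0340 to 0.127), and intensities were not analysed here. Among the 8 sign patterns of the 4 arrays, 1 gave as many genes past the test as the real one, itself included. The real pattern gave 1 gene against at most 0 in the others, and 561 against at most 11 without the dye term. Apart from the real one, only the pattern that sets arrays 1 and 2 against arrays 3 and 4 keeps each pair together. It gave 0 genes, and 11 without the dye term. The others oppose arrays that correlate strongly, so their count of 0 was nearly fixed in advance. With 8 patterns a share under 0.05 cannot be reached. The response to salt, as the design names it, is the biological explanation and remains a hypothesis.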

How the results depend on the processing

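The pair blocks and averages, probes tested apart and turned signs were added after the data were seen. The count of genes past the test was 1, and again 1 with no block, no centring, values on at least 3 arrays, a 2-fold minimum if the base is 10, pairs of arrays as random blocks, and each probe apart. It was 0 with scale normalization, with the shared-extract correlation fixed at 0.5, with robust and trended moderation, with a 2-fold minimum if the base is 2, with the averages of arrays 1 and 2 and of arrays 3 and 4, and with signs turned on arrays with salt in Cy3. It was 3 with quantile normalization, 119 at an adjusted p under 0.10 (79 positive), 125 with a t-test without moderation, 561 with no dye term and 2898 with arrays that share an extract averaged. That last average cancels the difference between arrays 1 and 2 and arrays 3 and 4 by construction, so its spread is too small. For the others the cause was not tested. Leaving out 1 array gave 0 to 1 genes. The adjusted p of blr4637 ran from 1.47e-14 with those averages to 0.620 with the fixed correlation, before signs were turned. Of the lists 8 passed, 2 with fry, 0 with an estimated correlation (2 residual degrees of freedom) and 0 with signs turned, and 6 to 9 in the other settings. Ribosomal, flagellar, ATP synthase, complex I and cytochrome lists passed in each of those other settings of the preset test. The 2 lists that passed with fry were ribosomal proteins and cell wall and division. For those 8 lists 112 tests with the preset correlation, under the alternatives without turned signs, gave 105 with the same direction and call, 7 that lost the call and 0 that reversed. Among lists that did not pass, nitrogen fixation and fatty acid genes passed in some settings, type III secretion genes changed direction without array 1 or 2, and DNA repair genes without array 4. With signs turned, sigma factor, nodulation, type III secretion, exopolysaccharide and polyhydroxybutyrate genes changed direction. So did ribosomal protein, chemotaxis and cytochrome genes among the lists that passed. The dye effect gave 0 genes with no block, with scale normalization and with pairs of arrays as random blocks. The lowest r between arrays was 0.128, with 0.079 for Spearman and 0.129 after quantile normalization. Of 98 named genes 8 changed sign in 13 of 1666 values, under the alternatives without turned signs. Fits with 1 array left out keep the dye term. They weight both dye orientations equally, so their values are not plain means of the arrays left, and some sign changes can come from this weighting. With 1 array left out the ranges were -0.0017 to 0.066 for otsA (bll0322), -0.0031 to 0.014 for mscL (bll5071), -0.034 to 0.0042 for exoT (blr7577), -0.030 to 0.0044 for exoB (blr7578), -0.037 to 0.00998 for irr (bll0768), -0.027 to 0.012 for fur (bll0797), -0.036 to 0.028 for tonB (bll7071), which was 0.00075 with scale normalization, and -0.033 to 0.014 for phbB (bll0225). Signal over background was not analysed here.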

Other observations

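The groups and genes in this part were chosen after the values were seen, and their signs carry the same uncertainty as those of the report. Runs of neighbouring genes shared a direction. The highest means over 10 consecutive locus numbers were 0.15 at loci 4637 to 4646, which open with blr4637, and 0.13 at loci 4648 to 4657, which hold dnaJ (blr4653). Next came 0.12 at loci 2763 to 2772, where all 9 genes had positive means; these include fixN, fixO, fixQ and fixP for the cbb3 oxidase and fixG, fixH, fixI and fixS beside it. A mean of 0.11 was found at loci 6061 to 6070, which open with fixK. Each had a permutation p of 0.001 against shuffled gene order, the smallest these shuffles can give. The lowest means were -0.094 at loci 6996 to 7005, with flgD, fliF, fliG and fliN, -0.094 at loci 1432 to 1441, with 8 genes of symbol ctp (ctpB to ctpI), and -0.094 at loci 5842 to 5851, with no gene symbol and all 10 means negative, each again with a permutation p of 0.001. A shuffle breaks up operons, so these p-values do not compare a run with other operons.

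Flagellar genes differed by their place on the chromosome. The 14 at loci 5809 to 5838 had a median of -0.095, with 13 negative on 4 of 4 arrays, and the 4 at loci 6997 to 7002 had -0.11, all negative on 4 of 4 arrays. The 24 at loci 6850 to 6885 had -0.011, with 5 negative on 4 of 4 arrays, and medians of 0.014, 0.017, -0.021 and -0.028 on arrays 1 to 4. The difference between these places was not tested.

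Grouping genes by the first letters of their symbols gave 79 groups with at least 5 genes, of which 13 passed limma's camera test with a preset correlation, 3 above and 10 below the other genes, and 0 with an estimated correlation. The groups above were nap for periplasmic nitrate reductase (5 genes, all positive, median 0.14, adjusted p = 0.00328), fix (22 genes, median 0.0095, adjusted p = 0.0277) and nos for nitrous oxide reduction (7 genes, 6 positive, median 0.039, adjusted p = 0.0351). With an estimated correlation, a test with 2 residual degrees of freedom and little power, the adjusted p was 0.738 for each of the 3. The nap medians were 0.18 and 0.20 on arrays 1 and 2 and 0.026 and 0.058 on arrays 3 and 4. Below lay ctp (14 genes, median -0.070, adjusted p = 0.00173) and cox (11 genes, median -0.039, adjusted p = 0.0309), each with an adjusted p of 0.738 with an estimated correlation.

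Of 8 genes of symbol hsp, for small heat shock proteins, 6 were positive on arrays 1 and 2 and negative on arrays 3 and 4, and 1, hspH (bll0729), was positive on all 4. The gene hspB (blr5233) had 0.18, 0.15, -0.19 and -0.15 on arrays 1 to 4, and hspE (blr5220) had 0.14, 0.24, -0.080 and -0.15. The regulator gene nifA (blr2037) had -0.071, -0.011, 0.25 and 0.27.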
